A study of Mus musculus with 6 samples.

How the data were processed

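Messenger RNA of the distal colon was sequenced from 6 male mice aged 8 weeks, 3 wildtype C57Bl/6 and 3 lacking TNFR2, the second receptor for tumor necrosis factor, whose gene is Tnfrsf1b. Per the labels, the 3 libraries of each genotype came from separate mice (n = 3 each), and library preparation included mRNA enrichment. The group and replicate number of each library were taken from the labels, and every library had a group.

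The deposited table holds 1 value per gene and library in FPKM, per the file headers, that is, fragments scaled to transcript length and to the number of mapped fragments. Per the series' design text, the authors aligned paired-end reads with Tophat2 and Bowtie2, assembled the alignments with Cufflinks and tested the genotypes with Cuffdiff 2, calling genes at a q-value under 0.05. The genome build was mm10, per the submitters' processing notes. The releases of Tophat, Bowtie and Cufflinks, the gene annotation, the strandedness of the libraries and the scaling between libraries are not given in the sources used here. The ratio of the authors' group FPKM values to the mean of the 3 libraries had a median of 0.997 in both genotypes. Single rows differ from this, among them called small RNA genes. Of the 24617 rows of the authors' deposited table, 3777 had a p-value and an adjusted p-value of 1 and a log2 fold change listed at 0, whatever their group values. In the other rows the log2 fold change is the log2 ratio of the group values, which held in all 19928 with both groups above 0, and 912 with a group at 0 carried a placeholder.

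Per the series' design text, average depth was 50M paired-end reads of 50 bp. FPKM values are not read counts, so the total of each library is unknown from the table. Genes with few fragments take values that are whole multiples of what 1 fragment is worth, and these steps gave the relative depth of the libraries. Taking wildtype library 1 as 1, relative depth was 1.02 and 0.736 in wildtype libraries 2 and 3, and 1.02, 0.874 and 1.10 in knockout libraries 1, 2 and 3. By this measure the deepest library had 1.50 times the depth of the shallowest, wildtype library 3. The steps give depth only if FPKM were scaled by mapped fragments alone, and the scaling between libraries is not given. Short genes and genes with few fragments are the least precise, and no counting interval was computed for any value.

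The analysis plan assumed that the table would most likely hold group values only, and named limma as the test where FPKM per library were found. The latter was the case, so limma was used as planned. Values were tested as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with an intensity trend and robust variance moderation, no covariates and all 6 libraries. Fold changes on this scale are knockout minus wildtype and understate the change of genes with low values. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 14564 in all, and called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values below are from limma unless another test is named. Rows with no gene name, 6.13% of the table and 17.7% of the summed FPKM, were left out of the tests. A further 340 rows named several genes and 641 named rows shared their symbol with another row; these stayed in. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The test was tried on simulated libraries with each gene's real spread and 200 changed genes among 14564. It recovered 30% of changes of 0.5 on the log2 scale, 88.5% of changes of 1 and 96% of changes of 2, with 3, 13 and 5 other genes called. The changed genes all had a mean of at least 2 FPKM, and noise was drawn separately for each gene. Recovery of lower genes, or with spread shared between genes, was not simulated.

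Genes were named by a rule fixed, like the gene lists and the tests, before the data were examined. It took Tnfrsf1b, the 12 called genes with the highest and the 12 with the lowest log2 ratio of group means (0.1 added to each) with at least 1 FPKM in the higher group, the 4 called genes with the smallest p not yet named, up to 4 called members of each gene list, and for a list with none called its 2 most highly expressed members. Small RNA genes, predicted genes and rows of several genes were left out of the ranking and kept in the counts. Other genes that the text names were chosen after their values were seen. Gene positions are from the RefSeq annotation of GRCm38.p6, the same assembly as mm10: of 22535 rows matched to it by symbol or synonym, 98.7% overlapped the position in the deposited table.

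Gene lists, 33 in number, covered pathways and cell types of the colon wall and of neighbouring tissue. Called members were counted per list and compared with all other tested genes by Fisher's exact test. Members were also adjusted over the list alone. The 31 lists with at least 3 tested members entered camera with a correlation of 0.01 between genes, camera with an estimated correlation, and fry, all with Benjamini-Hochberg adjustment over lists. Lists of skin and of hair follicle genes were added after the data were seen and were tested apart. Calls within 10 Mb of Tnfrsf1b were compared with calls elsewhere by Fisher's exact test, two-sided.

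The alternatives tried were thresholds of 0.01 and 0.1, a change of at least 2-fold, a minimum of 1 FPKM, no minimum, a pseudocount of 0.1, removal of small RNA genes, removal of rows with several or repeated symbols, windows of 5 and 20 Mb, the replicate number as a block, each library left out in turn, and the authors' deposited p-values adjusted anew. Added after the data were seen were the authors' q-values, the rows with no gene name, equal library medians, the mean of the skin list as a covariate, and a fit without the 3 libraries that differed most in skin and muscle genes.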

Results

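The comparison asks how the colon transcriptome of mice without TNFR2 differs from that of wildtype mice. Gene expression was measured by mRNA sequencing in the distal colon of 3 wildtype and 3 TNFR2 knockout males aged 8 weeks, and values are given in FPKM. Stated depth averaged 50M paired-end reads of 50 bp per sample. Summed FPKM ranged from 655274 to 709593 per library, and between 12974 and 13625 named rows reached 1 FPKM. Relative depth, as judged from the steps of low values, differed up to 1.5-fold.

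Tnfrsf1b, the targeted gene (chromosome 4, 145212368 to 145246870, mm10), measured 7.49, 8.20 and 8.17 FPKM in the wildtype libraries and 1.17, 1.12 and 0.924 FPKM in the knockout libraries. Its mean fell from 7.95 ± 0.398 to 1.07 ± 0.131 FPKM (SD, n = 3 each), 13.5% of wildtype, a log2 change of -2.11 ± 0.08 (SE; limma, Benjamini-Hochberg adjusted p = 7.1e-05). The deleted part of the gene is not given in the sources used here, so the remaining signal cannot be assigned to exons. All 6 libraries carried the values their labels imply.

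Libraries also differed in genes of tissues that border the distal colon. Median expression of 37 skin genes, a list added after the data were seen, was 37.3, 17.6 and 56.3 FPKM in the wildtype libraries and 1.8, 23.2 and 23.4 FPKM in the knockout libraries. For 49 hair follicle genes, also added afterwards, the medians were 10.6, 2.41 and 16.6 against 0.162, 0.387 and 2.57 FPKM. For the 10 skeletal muscle genes of the preset list they were 1321, 399 and 484 against 18.5, 308 and 203 FPKM. Krt14, a keratin of basal skin cells, ranged from 43.5 to 140 FPKM in wildtype and from 6.04 to 69.4 FPKM in knockout libraries, and Ckm, muscle creatine kinase, from 416 to 1359 and from 38.2 to 324 FPKM. Knockout library 1 was lowest and wildtype libraries 1 and 3 were highest in all 3 groups of genes. The first principal component, 55.2% of the variance, placed the wildtype libraries at -37.1, -6.71 and -33.4 and the knockout libraries at 46.3, 13.0 and 17.9.

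**Figure D1:**
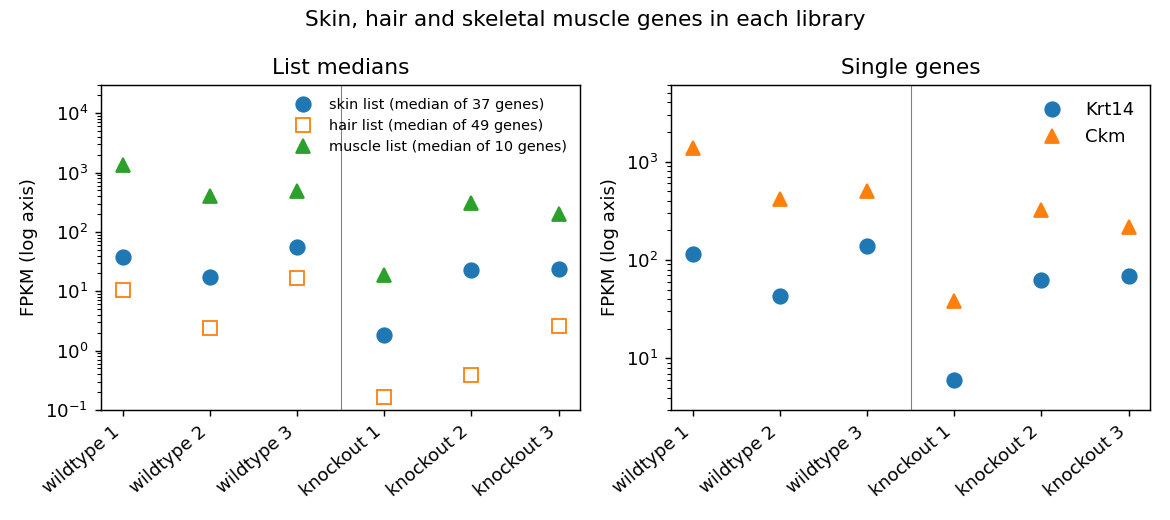
FPKM (log axis) in each of the 6 libraries, as medians of the skin, hair follicle and skeletal muscle lists (left) and for the single genes Krt14 and Ckm (right), each point 1 library. Knockout library 1 lies lowest in every series, with a skin median of 1.8 FPKM against 56.3 FPKM in wildtype library 3.

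Besides Tnfrsf1b, 11 ordinary named genes rose and 9 fell in the knockout colon. Gbp1, a member of the interferon-inducible GTPase family on chromosome 3 (142594816 to 142619179, named Gbp2b in the reference annotation), rose from 0.294 ± 0.068 to 11.1 ± 0.996 FPKM (SD, n = 3 each), 37.8-fold. Slc37a2, a sugar phosphate transporter of the endoplasmic reticulum (chromosome 9, 37229149 to 37255738), rose 2.84-fold, from 26.1 ± 1.07 to 74.1 ± 9.58 FPKM. Adh1, an alcohol dehydrogenase that also oxidises retinol (chromosome 3, 138277585 to 138290698), rose 2.01-fold, from 661 ± 50.1 to 1325 ± 93.8 FPKM. Nr4a1, an orphan nuclear receptor of the immediate early class (chromosome 15, 101253902 to 101274795), fell from 19.4 ± 3.56 to 7.31 ± 0.877 FPKM, 37.6% of wildtype. Ccdc109b, which encodes a subunit of the mitochondrial calcium uniporter (Mcub in the reference annotation, chromosome 3, 129914960 to 129970211), fell from 3.53 ± 0.111 to 1.03 ± 0.0936 FPKM, 29.2% of wildtype.

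In limma with Benjamini-Hochberg adjustment these log2 changes were 3.23 ± 0.09 (SE, adjusted p = 1.3e-05) for Gbp1, 1.46 ± 0.10 (adjusted p = 0.0020) for Slc37a2, 1.00 ± 0.09 (adjusted p = 0.0069) for Adh1, -1.29 ± 0.14 (adjusted p = 0.020) for Nr4a1 and -1.16 ± 0.08 (adjusted p = 0.0017) for Ccdc109b. Gbp1 has close relatives in the genome, and how reads shared between copies were counted is not given in the sources used here. The neighbouring Gbp2 measured 11.9 ± 1.53 FPKM in wildtype and 11.8 ± 1.01 FPKM in knockout libraries, and Gbp3 3.64 ± 0.314 and 3.94 ± 0.614 FPKM.

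Other genes that rose were Efna3, a ligand of Eph receptors (3.71-fold), Eaf2, a transcription elongation factor partner (2.31-fold), the homeobox gene Rhox8 (2.06-fold), Neil3, a DNA glycosylase (1.73-fold), Mettl7a3 (1.70-fold), the dynein light chain gene Dynlt1b (1.61-fold) and Ano1, a calcium-activated chloride channel of the pacemaker cells of the gut wall (1.48-fold). Ano1 was the most highly expressed of these, with 53.0 ± 3.03 FPKM in wildtype and 78.5 ± 1.90 FPKM in knockout libraries (SD, n = 3 each). In the authors' deposited table Ano1 has a p-value of 1 and a log2 fold change listed at 0. The log2 changes of these genes lay between 0.56 ± 0.07 for Ano1 and 1.20 ± 0.14 for Efna3 (SE), with limma, Benjamini-Hochberg adjusted p-values between 0.018 and 0.041. The symbol Efna3 fills 3 rows at 1 locus, and the others, at 1.19 and 4.54 FPKM in wildtype and 3.30 and 3.66 FPKM in knockout libraries, did not pass (limma, Benjamini-Hochberg adjusted p = 0.159 and 0.313). Mettl7a3 and Dynlt1b have near-identical copies in the genome and are uncertain for that reason.

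Genes that fell included Hmox1, the inducible heme oxygenase, from 9.67 ± 0.725 to 4.77 ± 0.562 FPKM (SD, n = 3 each), and Ide, the insulin-degrading enzyme, from 21.8 ± 1.98 to 10.3 ± 1.60 FPKM. Btaf1, an ATPase that removes TATA-binding protein from DNA, lies close to Ide on chromosome 19 and fell from 11.7 ± 2.10 to 5.04 ± 0.643 FPKM. Ide and Btaf1 stood at 47.0% and 43.0% of wildtype, and whether they are separate changes was not tested. Tmem41b, a lipid scramblase needed for autophagosome formation, fell from 14.1 ± 0.645 to 8.36 ± 0.522 FPKM. The log2 changes of these 4 genes were -0.89 ± 0.10, -1.03 ± 0.12, -1.07 ± 0.14 and -0.69 ± 0.07 (SE), with limma, Benjamini-Hochberg adjusted p-values of 0.019, 0.023, 0.044 and 0.017. In the authors' deposited table Ide has a p-value of 1 and a log2 fold change listed at 0.

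**Figure D2:**
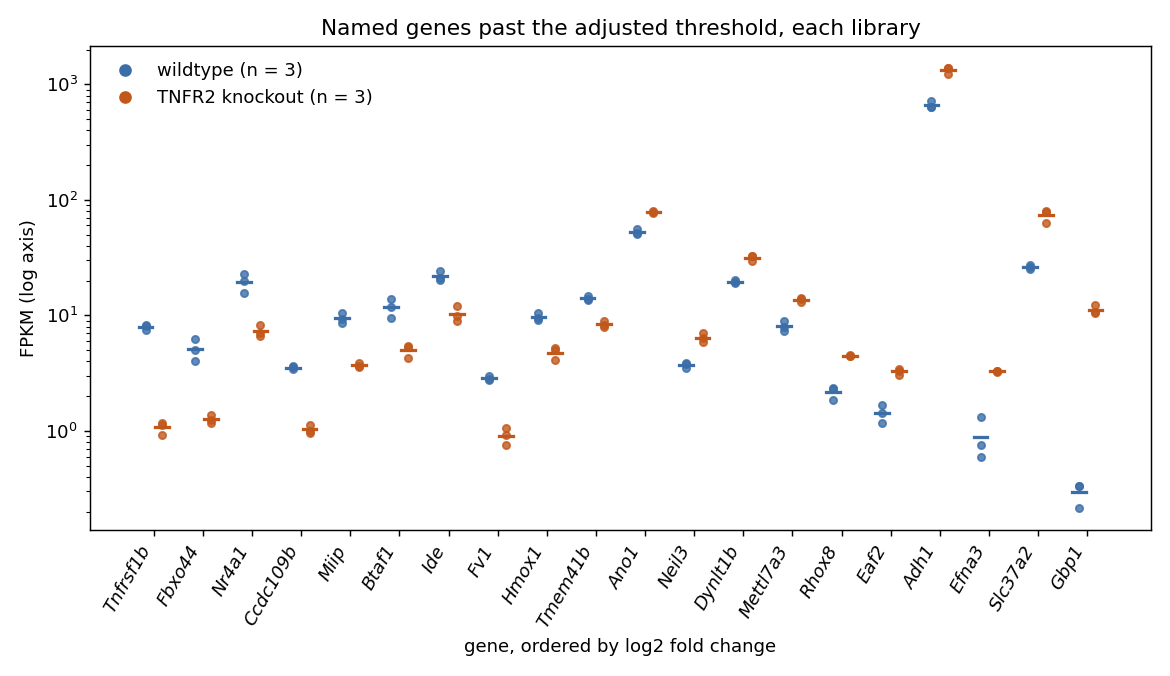
FPKM (log axis) of 20 of the 21 ordinary named genes past the adjusted threshold in wildtype (blue) and TNFR2 knockout (orange) colon, ordered by log2 fold change; points are single libraries (n = 3 per group) and bars are group means. The groups do not overlap for any of them, from Tnfrsf1b at 7.95 against 1.07 FPKM to Gbp1 at 0.294 against 11.1 FPKM.

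In all, 42 of 14564 tested genes passed the adjusted threshold in limma, 27 higher and 15 lower in the knockout, and 2360 had an unadjusted p under 0.05. Wildtype and knockout values did not overlap for 21.8% of the tested genes, where chance gives 10% on average. Genes vary together, so the share can lie far from 10% by chance, and its spread was not computed. Of the 42, 21 were ordinary named genes, 6 were predicted genes, 1 was a row of several genes and 14 were small RNA genes, 11 higher and 3 lower. Among the small RNA genes, chosen as examples after their values were seen, Snord65 measured 0, 0.333 and 0 FPKM in wildtype and 382, 445 and 353 FPKM in knockout libraries. Snord4a measured 140, 205 and 190 FPKM in wildtype and 0, 0.317 and 0 FPKM in knockout libraries. All 14 have a q-value near 1 in the authors' deposited table, where Snord65 has a log2 fold change of 1.60 and Snora5c, called lower in limma, has 0.18. Predicted gene 2210415F13Rik (Lypd8 in the reference annotation, chromosome 11, 58377546 to 58392840) is named here after its values were seen. It measured 6008, 8488 and 6670 FPKM in the wildtype libraries and is listed at 0 in all 3 knockout libraries, with a p-value of 1 in the authors' deposited table. Whether a listed 0 is a measured absence or a failed estimate is not known from the table.

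A fit without the 3 libraries that differed most in skin and muscle genes (wildtype 1 and 3, knockout 1) was chosen after seeing the data. It leaves a lone wildtype library, whose spread cannot be estimated, so its count of calls is not given. With the mean of the skin list as a covariate, also chosen afterwards, 25 genes were called. Leaving out single libraries moved the count between 21 and 74. Of the 21 ordinary named genes Tnfrsf1b, Gbp1, Slc37a2, Ccdc109b and Miip were called in every such fit, while 16 lost their call in at least 1. Without small RNA genes, Eaf2, Neil3, Mettl7a3, Ano1 and Btaf1 lost their call (limma, Benjamini-Hochberg adjusted p = 0.0501 to 0.0562). With the skin covariate, 13 of the 20 ordinary named genes besides Tnfrsf1b lost theirs. That covariate itself differs between the genotypes, so these losses do not show that the genes depend on skin tissue. The replicate number as a block lost 14 of the 20.

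Around Tnfrsf1b on chromosome 4, the knockout libraries had lower levels of Miip, an inhibitor of cell migration, of Fv1, a restriction factor against murine leukemia virus, and of Fbxo44, an F-box subunit of ubiquitin ligases. Miip (147860778 to 147868719) fell from 9.45 ± 0.882 to 3.71 ± 0.177 FPKM (SD, n = 3 each), Fv1 (147868979 to 147870358) from 2.86 ± 0.141 to 0.913 ± 0.156 FPKM and Fbxo44 (148152799 to 148160183) from 5.10 ± 1.08 to 1.27 ± 0.109 FPKM. The predicted gene Gm13139 fell from 3.07 ± 0.199 to 1.37 ± 0.0544 FPKM, and 2610109H07Rik (Draxin in the reference annotation) is listed at 0 in the 3 wildtype libraries and measured 3.78, 1.72 and 1.67 FPKM in the knockout libraries.

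In limma with Benjamini-Hochberg adjustment, the log2 changes were -1.15 ± 0.08 (SE, adjusted p = 0.0022) for Miip, -1.01 ± 0.09 (adjusted p = 0.0085) for Fv1 and -1.41 ± 0.14 (adjusted p = 0.011) for Fbxo44. Within 10 Mb of Tnfrsf1b, 6 of 199 tested genes were called (3.02%), against 35 of 14364 elsewhere (0.244%), an odds ratio of 12.7 (95% interval 4.32 to 31, Fisher's exact test, two-sided, p = 1.8e-05). Miip and Fv1 lie side by side, and whether the libraries kept the strand of each read is not given in the sources used here. Without knockout library 3, 1 of 200 genes in the window was called and the odds ratio was 3.79 (Fisher's exact test, p = 0.24).

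**Figure D3:**
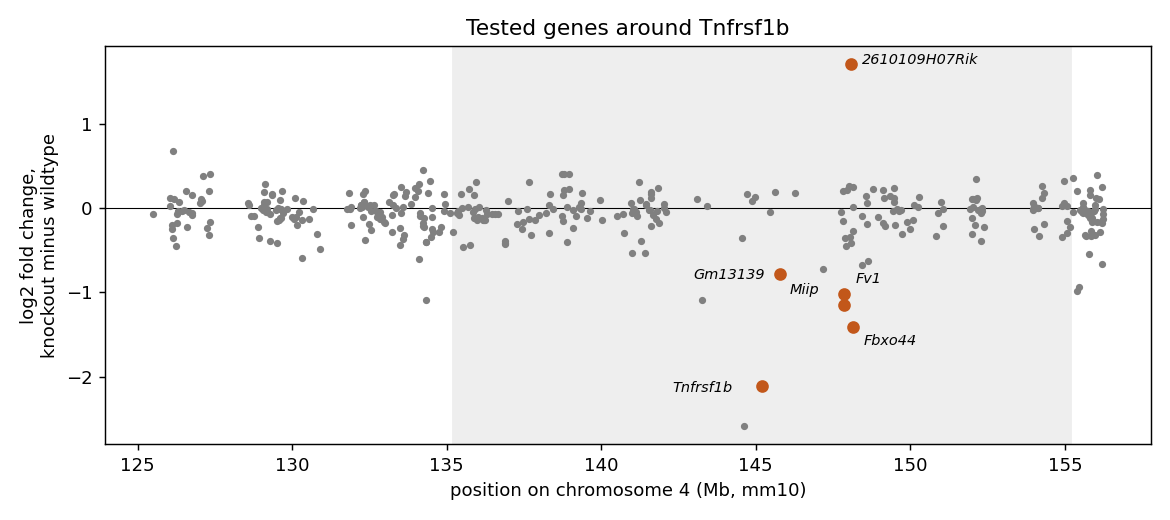
Log2 fold change on the log2(FPKM + 1) scale, knockout minus wildtype, of each tested gene (points) by its position on chromosome 4 in Mb (mm10), with called genes in orange, 1 called gene left out, and the window of 10 Mb on either side of Tnfrsf1b shaded. Apart from Tnfrsf1b at -2.11, called genes within the window run from -1.41 (Fbxo44) to 1.70 (2610109H07Rik, listed at 0 in wildtype).

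TNF signalling genes other than the targeted receptor did not pass the test. Tnf itself measured 0.561 ± 0.0501 FPKM in wildtype and 0.554 ± 0.133 FPKM in knockout libraries (SD, n = 3 each), and Tnfrsf1a, the other TNF receptor, 60.3 ± 1.83 and 50.9 ± 3.99 FPKM. Tradd and Ltbr, the most highly expressed of the 21 tested genes of TNF and NF-kB signalling, measured 85.4 ± 10.7 and 57.6 ± 2.01 FPKM in wildtype against 90.6 ± 8.90 and 57.4 ± 5.29 FPKM in knockout libraries. None of the 21 was called in limma over all genes or adjusted over the list alone.

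The MHC class II list and the macrophage and monocyte list were called lower by camera in the knockout colon (adjusted p = 0.0005 each), and both calls were lost with an estimated correlation (adjusted p = 0.693 each). All 8 tested MHC class II genes had lower means, with a median log2 change of -0.49. Cd74, the invariant chain, measured 325 ± 2.58 FPKM in wildtype and 200.3 ± 50.8 FPKM in knockout libraries, and the class II chain gene H2-Aa 128 ± 13.3 and 89.4 ± 18.6 FPKM (SD, n = 3 each). Of 15 macrophage and monocyte genes 14 had lower means, with a median log2 change of -0.37. Lyz2, a lysozyme of myeloid cells, measured 222 ± 21.1 and 148 ± 32.4 FPKM, and C1qa, a complement subunit, 81.1 ± 7.33 and 61.0 ± 11.5 FPKM. No member was called over all genes in limma; adjusted over the list alone, 6 MHC class II genes and 0 macrophage genes were lower. Skin list medians beside these were 37.3, 17.6 and 56.3 FPKM in the wildtype libraries and 1.8, 23.2 and 23.4 FPKM in the knockout libraries, with wildtype library 2 below knockout libraries 2 and 3.

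Of 14 tested inflammatory genes 11 had lower and 3 higher means in the knockout, with a median log2 change of -0.25, and camera did not call the list (adjusted p = 0.061). Adjusted over the list alone, 1 was higher and 4 were lower, and none was called over all genes. Saa1, an acute phase gene whose row also names Saa3, was higher at 1507 ± 328 FPKM in knockout against 735 ± 149 FPKM in wildtype libraries, and the chemokines Ccl2 and Ccl7 and the adhesion genes Icam1 and Vcam1 were lower. Ccl2, which attracts monocytes, measured 4.06 ± 0.559 FPKM in wildtype and 1.67 ± 0.349 FPKM in knockout libraries (SD, n = 3 each), and its limma, Benjamini-Hochberg adjusted p was 0.058 over all genes and 0.0028 adjusted over the list alone. Of 24 interferon response and antigen processing genes none was called over all genes, and 1, Ifit3, was lower adjusted over the list alone (3.55 ± 0.776 against 1.81 ± 0.282 FPKM). Irf1 measured 58.5 ± 9.94 and 69.3 ± 5.38 FPKM and Irf7 29.5 ± 3.54 and 34.5 ± 3.44 FPKM.

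Of 17 CD8 and cytotoxic lymphocyte genes 3 reached the minimum for testing and none was called, over all genes or adjusted over the list alone. Cd8a averaged 0.148 ± 0.0476 FPKM in wildtype and 0.111 ± 0.0233 FPKM in knockout libraries (SD, n = 3 each) and was not tested. Ccl5, the highest of the 3, measured 3.90 ± 0.467 and 2.98 ± 1.70 FPKM, and Klrd1 0.854 ± 0.128 and 0.868 ± 0.248 FPKM. Of 4 tested T cell genes 2, Cd2 and Cd4, were lower adjusted over the list alone and none over all genes. Cd4 measured 1.85 ± 0.26 and 1.18 ± 0.158 FPKM. None of 4 regulatory T cell genes, 11 B cell genes or 5 plasma cell genes was called, over all genes or adjusted over the list alone, although all 11 B cell genes had lower means in the knockout. Cd79a, a part of the B cell receptor, spanned 2.63 to 7.54 FPKM in wildtype and 0.894 to 6.78 FPKM in knockout libraries, and Cd79b measured 4.12 ± 1.85 and 2.53 ± 1.85 FPKM. Sdc1 and Igj of the plasma cell list measured 68.2 ± 4.12 and 30.4 ± 6.44 FPKM in wildtype against 56.7 ± 8.07 and 23.0 ± 4.51 FPKM in knockout libraries. Lrrc32 of the regulatory T cell list measured 6.37 ± 1.11 and 4.58 ± 0.975 FPKM, and Tnfrsf4, whose row also names Sdf4, 37.8 ± 0.635 and 37.4 ± 2.16 FPKM. Which cells these values come from was not tested.

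The cell cycle list was called higher by camera (adjusted p = 0.00023), and the call was lost with an estimated correlation (adjusted p = 0.693). Of 20 cell cycle genes 12 had higher means in the knockout, with a median log2 change of 0.38. Mki67, Ccnb2 and Cdc20, genes of dividing cells picked after their values were seen, measured 12.7 ± 0.705, 14.8 ± 0.708 and 12.2 ± 0.855 FPKM in wildtype against 20.1 ± 3.15, 24.7 ± 3.87 and 19.7 ± 3.08 FPKM in knockout libraries (SD, n = 3 each). Pcna, the most highly expressed member, measured 120 ± 12.9 and 112 ± 6.45 FPKM, and 8 members had lower means. Adjusted over the list alone, 10 genes were higher, among them Mki67, Ccnb2, Cdc20 and the kinase gene Plk1, and none passed over all genes. Without the 3 libraries that differed most in skin and muscle genes camera did not call the list. That fit keeps a lone wildtype library and cannot decide the call. Beside these, the muscle list median was 399 to 1321 FPKM in wildtype and 18.5 to 308 FPKM in knockout libraries.

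Camera called the goblet cell and surface colonocyte lists higher (adjusted p = 0.0071 and 0.015), and both calls were lost with an estimated correlation (adjusted p = 0.693 each). In these lists 11 of 12 and 15 of 17 genes had higher means, with median log2 changes of 0.20 and 0.13. Zg16 and Tff3, secreted goblet cell products, measured 2162 ± 325 and 1715 ± 202 FPKM in wildtype and 2539 ± 722 and 2020.0 ± 421 FPKM in knockout libraries (SD, n = 3 each). The carbonic anhydrase genes Car1 and Car4 measured 1028 ± 174 and 770 ± 129 against 1354 ± 363 and 844 ± 146 FPKM. No member was called over all genes or adjusted over the list alone. Without the 3 libraries that differed most in skin and muscle genes, the medians turned to -0.13 and -0.10. That fit sets wildtype library 2 alone against knockout libraries 2 and 3. Of the libraries kept, wildtype 2 had the lowest skin list median (17.6 against 23.2 and 23.4 FPKM). Camera also lost the goblet cell list without knockout library 1 (adjusted p = 0.167) and with the skin covariate (adjusted p = 0.671). It lost the surface colonocyte list without wildtype library 1, wildtype library 3 or knockout library 1 and with the skin covariate (adjusted p = 0.069, 0.080, 0.056 and 0.322). Skin list medians beside them were 17.6 to 56.3 FPKM in wildtype and 1.8 to 23.4 FPKM in knockout libraries.

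Camera called the fibroblast, endothelial, adipocyte, and enteric neuron and glia lists lower (adjusted p = 0.00012, 0.00023, 0.00023 and 0.040), and lost each with an estimated correlation (adjusted p = 0.693 for the first 3 and 0.747 for neurons and glia). All 13 fibroblast and matrix genes, all 10 endothelial genes and all 10 adipocyte genes had lower means in the knockout, with median log2 changes of -0.39, -0.34 and -0.72. Sparc and Col3a1, matrix proteins, measured 547 ± 89.6 and 455 ± 53.1 FPKM in wildtype and 382 ± 50.6 and 347 ± 38.5 FPKM in knockout libraries (SD, n = 3 each). Plvap and Lyve1, genes of blood and lymph vessels, measured 29.7 ± 1.86 and 23.5 ± 3.30 against 24.2 ± 3.30 and 17.6 ± 4.19 FPKM, and the fat cell genes Fabp4 and Cfd 136 ± 31.5 and 40.6 ± 14.6 against 71.8 ± 7.86 and 13.9 ± 7.37 FPKM. Of 13 genes of enteric neurons and glia 12 had lower means, with a median of -0.24. Vip, a neuropeptide gene, measured 27.1 ± 6.68 and 22.3 ± 4.93 FPKM, and Uchl1, a marker of neurons, 24.0 ± 5.15 and 20.2 ± 3.78 FPKM.

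No member of these 4 lists was called over all genes in limma; adjusted over the list alone, 9 fibroblast, 6 endothelial, 6 adipocyte and 0 neuronal and glial genes were lower. The neuronal and glial median turned to 0.13 without the 3 libraries that differed most in skin and muscle genes. Camera no longer called the fibroblast and endothelial lists there, but that fit keeps a lone wildtype library and cannot decide those calls. Camera lost the neuronal and glial list without wildtype library 1, wildtype library 3 or knockout library 1 and with the skin covariate (adjusted p = 0.282, 0.088, 0.392 and 0.993). Beside these groups, skin, hair follicle and muscle genes had the following levels: the lowest wildtype medians of the 3 lists were 17.6, 2.41 and 399 FPKM, and the highest in the knockout 23.4, 2.57 and 308 FPKM.

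Among the preset lists, skeletal muscle genes had the largest median change on the log2(FPKM + 1) scale, -2.45 over 10 genes. All 10 were lower in every knockout library than in every wildtype library. This scale understates the change of genes with low values, such as those of hair follicle, so it does not rank muscle above hair by fold in FPKM. Acta1, skeletal actin, measured 1840.0, 607 and 732 FPKM in the wildtype libraries and 37.7, 428 and 358 FPKM in the knockout libraries, and Tnnc2, a troponin of fast muscle, 1645, 505 and 639.8 against 29.5, 449 and 399.5 FPKM. Camera called the list lower (adjusted p = 0.00023) and lost it with an estimated correlation (adjusted p = 0.693). No muscle gene was called in limma, over all genes or adjusted over the list alone. The added lists had median log2 changes of -1.24 over 37 skin genes and -2.37 over 42 tested hair follicle genes, all with lower means in the knockout and none called in limma. With an estimated correlation camera gave p = 0.41 and 0.17. All 10 muscle, 16 skin and 44 hair follicle genes were called lower in the authors' deposited table.

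**Figure D4:**
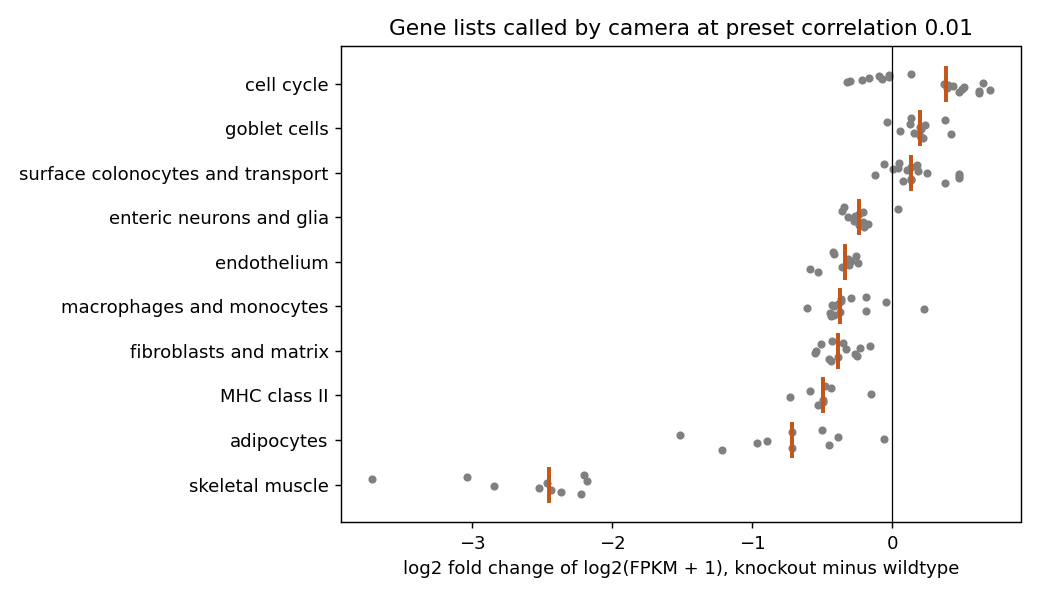
Log2 fold change on the log2(FPKM + 1) scale, knockout minus wildtype (n = 3 each), of each tested member (grey points) of the 10 preset gene lists called by camera at a preset correlation of 0.01, with list medians as orange bars. Medians run from -2.45 for skeletal muscle to 0.38 for the cell cycle, whose members fall into a higher and a lower set.

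The remaining preset lists were not called by camera, with adjusted p-values between 0.061 and 0.865. Among 14 immediate early genes Nr4a1 fell, as described, and Fosb was lower adjusted over the list alone (4.59 ± 0.68 against 2.75 ± 0.589 FPKM; SD, n = 3 each). Of these genes 9 had lower and 5 higher means. Fos, named after its values were seen, measured 31.1, 38.9 and 37.2 FPKM in the wildtype libraries and 40.1, 52.9 and 84.7 FPKM in the knockout libraries, was not called in limma (Benjamini-Hochberg adjusted p = 0.311) and was called higher in the authors' deposited table. Of 11 antimicrobial genes of the epithelium that were matched and tested, none was called over all genes. Lyz1, a lysozyme, was lower adjusted over the list alone (40.2 ± 4.49 against 28.0 ± 1.46 FPKM). Lypd8 was also on this preset list, but its row carries the name 2210415F13Rik and was not matched. Its call, described above, is therefore missing from the counts of called list members. Pigr, which carries immunoglobulin across the epithelium, measured 509.6 ± 69.5 and 689 ± 111 FPKM, and Dmbt1, a mucosal defence gene, 346 ± 54.8 and 418 ± 66.4 FPKM. Adjusted over the list alone, 1 of 14 crypt base genes (Cd44), 1 of 6 tuft cell genes (Alox5ap), 2 of 17 fatty acid oxidation genes (Cd36 and Angptl4) and both tested red blood cell genes were lower, and none of them passed over all genes. No gene of the enteroendocrine (10 tested), smooth muscle (13), exocrine pancreas (3), circadian clock (15), unfolded protein response (11), xenobiotic metabolism (19), sterol synthesis (17) or sex-linked (4) lists was called either way, and no mesothelial gene reached the minimum. Over all 31 lists tested, fry called none in 1 direction and 2 in either direction, inflammatory (adjusted p = 0.025) and immediate early genes (adjusted p = 0.00049). After adjustment over lists, Fisher's exact test found no list with more called members than other genes. The lowest was immediate early genes, with 1 of 14 called lower (Fisher's exact test, p = 0.014, adjusted p = 0.459).

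The most highly expressed members of these lists gave the following means. Pyy and Insl5, hormone genes of enteroendocrine cells, measured 182 ± 18.4 and 57.9 ± 23.7 FPKM in wildtype and 231 ± 48.7 and 76.7 ± 28.6 FPKM in knockout libraries (SD, n = 3 each). Tagln and Actg2 of smooth muscle measured 2416 ± 553 and 1859 ± 417 against 2054 ± 352 and 1667 ± 310.3 FPKM, with lower means for all 13 genes of that list. The clock genes Nr1d1 and Arntl measured 25.4 ± 5.97 and 26.7 ± 2.94 against 37.4 ± 7.73 and 24.6 ± 4.61 FPKM. Hspa5 and Atf4 of the unfolded protein response measured 169 ± 9.88 and 87.1 ± 1.29 against 150.3 ± 11.6 and 83.3 ± 4.84 FPKM. Cyp2c55 and Gstm1, enzymes of xenobiotic metabolism, measured 522 ± 74.6 and 223 ± 11.1 against 471 ± 60.8 and 241 ± 23.4 FPKM. Ucp2 and Acadl of fatty acid oxidation measured 134 ± 12.9 and 92.5 ± 4.84 against 132 ± 13.5 and 93.6 ± 10.1 FPKM, and Hmgcs1 and Fdps of sterol synthesis 107 ± 9.29 and 97.0 ± 6.11 against 97.9 ± 5.76 and 96.5 ± 6.20 FPKM. Rgmb and Cdca7 of the crypt base measured 27.5 ± 3.78 and 23.7 ± 1.15 against 25.7 ± 2.46 and 21.5 ± 1.49 FPKM, and Avil of tuft cells, whose row also names Ctdsp2, 356 ± 147 against 421 ± 95.1 FPKM. Cela1 and Clps of the exocrine pancreas list measured 317 ± 39.2 and 43.0 ± 6.95 against 351 ± 39.4 and 45.2 ± 6.28 FPKM. Only 3 of the 13 members of that list reached the minimum for testing. Hba-a1, a hemoglobin chain in a row shared with Hba-a2, measured 47.7 ± 11.2 and 30.7 ± 7.02 FPKM. The Y-linked genes Eif2s3y and Ddx3y measured 33.1 ± 1.45 and 11.2 ± 0.641 against 34.5 ± 2.81 and 10.3 ± 0.65 FPKM.

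In the authors' deposited table, 240 named genes had a q-value under 0.05, 22 higher and 218 lower in the knockout. The lower genes in the authors' deposited table included 35 keratin-associated protein genes and 18 keratin genes, which build hair and skin. Among the higher genes, the authors' deposited table lists Gbp1, Slc37a2, Adh1 and Efna3, the acute phase genes Saa1 and Saa2, the kinase gene Camk2b, the inflammasome sensor gene Nlrp6 and the hydrogen peroxide source Duox2. Of these 240 genes, 232 were tested in limma, 117 had an unadjusted p under 0.05 and 12 passed after Benjamini-Hochberg adjustment, 6 higher and 6 lower. By direction, 19 of the 20 tested higher genes and 98 of the 212 tested lower genes of the authors' deposited table had an unadjusted limma p under 0.05.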

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

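The fit with the mean of the skin list as a covariate, the fit without wildtype 1, wildtype 3 and knockout 1, equal library medians, rows with no gene name and the authors' q-values were chosen after seeing the data; the other alternatives were planned. Against 42 called genes (27 higher, 15 lower), limma called 21 at an adjusted p under 0.01, 21 without small RNA genes, 25 with the skin covariate and 130 without the 3 libraries in doubt, where the lone wildtype library is assumed to vary like the knockouts. The authors' p-values gave 235 genes after a new adjustment, 238 at a mean of at least 0.5 FPKM and 223 at 1 FPKM, and the authors' q-values gave 240. Leaving out each library gave 21 to 74, moved by over 1.5 times without wildtype 1 (27), wildtype 2 (74), wildtype 3 (22) and knockout 3 (21). Members of the gene lists called, 1 as reported, were 0 at an adjusted p under 0.01, 2 under 0.10, 0 with no minimum, 0 to 2 with a library left out, 0 with the skin covariate, 17 without the 3 libraries in doubt and 19 by the authors' q-values. The odds ratio around Tnfrsf1b was 3.79 to 9.64 with a library left out and 1.54 by the authors' q-values (Fisher's exact test, p = 0.27). Without the 3 libraries in doubt the list medians turned to -0.13 for goblet cells, -0.10 for surface colonocytes and 0.13 for enteric neurons and glia. Apart from the fits with fewer libraries or other genes tested, the cause was not tested. Tnfrsf1b was called in the limma fits. Its log2 changes ran from -2.89 to -2.06, where -2.89 is the log2 ratio of group means with nothing added, which was not tested. None of the 21 ordinary named genes that were called turned direction. Of the 20 besides Tnfrsf1b, 5 lost their call without small RNA genes, 8 with no minimum and 13 with the skin covariate. A pseudocount of 0.1 lost 4 of the 20, and adding rows with no gene name lost 3. None of the 20 was lost with a minimum of 1 FPKM or with equal library medians. Single members of the lists that were not called were not followed. Of the 10 lists reported, camera kept 8 without wildtype 1, 8 without wildtype 3, 7 without knockout 1 and 7 with the skin covariate. The lists lost with 1 library out or the covariate were goblet cells, surface colonocytes, and enteric neurons and glia. Count-based tests were not run because the values are not counts. An average depth of 50M reads per sample is stated, without a total for each library, and the number of fragments behind a value near 0.5 FPKM was not computed.

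Replicate numbers were also entered as a replicate block, which gave 24 called genes, 14 higher and 10 lower. Of the 20 ordinary named genes besides Tnfrsf1b, 6 were called with the block and 14 were not. Libraries that share a number correlated at -0.37, -0.34 and 0.21 after removal of genotype means, and only wildtype 3 and knockout 3 correlated best with their own number, which does not show a pairing and does not rule it out.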

Other observations

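In this part the tests of calls clustered outside the window, of correlation and overlap of skin, hair follicle and muscle genes, of whole multiples and of other splits were chosen after the result was seen, and single genes were picked after their values were seen. Among the genes called higher in the authors' deposited table, Nlrp6, an inflammasome sensor gene, went from 31.5 to 52.0 FPKM and Duox2, a source of hydrogen peroxide, from 4.57 to 8.03 FPKM. Saa2, an acute phase gene, went from 46.5 to 90.0 FPKM in the authors' deposited table, and Camk2b, a calcium-dependent kinase gene, from 28.8 to 80.9 FPKM. In the 3 libraries of each genotype Camk2b measured 28.7 ± 8.62 and 80.5 ± 10 FPKM and Nlrp6 31.7 ± 6.89 and 52.3 ± 4.41 FPKM (SD, n = 3 each), and neither was called in limma (Benjamini-Hochberg adjusted p = 0.074 and 0.159).

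Next to Btaf1 on chromosome 19 lies Fgfbp3, a carrier of fibroblast growth factors, which measured 1.44, 2.07 and 2.29 FPKM in wildtype and 0.873, 0.902 and 0.76 FPKM in knockout libraries. Within the window of chromosome 4, Pdpn, a membrane protein of lymph vessels and stroma, measured 15.5 ± 1.99 FPKM in wildtype and 6.91 ± 2.22 FPKM in knockout libraries (SD, n = 3 each). Neither was called in limma (Benjamini-Hochberg adjusted p = 0.152 and 0.159). Fgfbp3 was lower in every knockout library than in every wildtype library. Whether a single change spans Fgfbp3, Btaf1 and Ide was not tested.

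Miip, Fv1, Fbxo44, Gm13139 and 2610109H07Rik are among the called genes within 10 Mb of Tnfrsf1b, an odds ratio of 12.7 for calls there (Fisher's exact test, p = 1.8e-05). DNA of the strain in which the gene was targeted, kept around it, could give this, and so could an effect of the deletion on its neighbours, which was not tested. Further such segments would gather calls elsewhere. The most calls in any span of 20 Mb outside the window was 3, for Ccdc109b, Adh1 and Gbp1 on chromosome 3 among others (permutation p = 0.28), so further segments of donor-strain DNA and scattered calls cannot be told apart with 21 calls. Spans of 20 Mb do not single out close neighbours such as Ide and Btaf1. The targeting strain and the backcross are not given in the sources used here.

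Skin, hair follicle and muscle genes vary together within a genotype, with mean correlations between members of 0.849, 0.894 and 0.937, as unequal pieces of neighbouring tissue might leave them. Lists of the colon wall reach the same level, such as smooth muscle at 0.972 and B cells at 0.943, against 0.264 for TNF and NF-kB signalling, so the correlations show that members vary together and not where their tissue comes from. For skin, every knockout library lay below every wildtype library for 5.41% of 37 genes. The median of wildtype library 2 (17.6 FPKM) lay below those of knockout libraries 2 and 3 (23.2 and 23.4 FPKM). Skin levels thus also differed within a genotype. Members that vary together count as few independent values, so the overlap does not exclude a genotype effect that differs between mice. The share of such genes was 50% for 42 hair follicle genes and 100% for 10 muscle genes. Genotype and carry-over cannot be told apart for any of the 3 lists with 3 libraries each. A difference in dissection between the genotypes was not tested apart from these values.

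The 14 small RNA genes called, such as Snord65, Snord4a, Mir3058 and Snord91a, took values in their expressed genotype that, scaled by relative depth, stood in ratios of small whole numbers to within 0.02 of a step. Genotypes with no value of 5 FPKM or more, such as wildtype for Snord65, and values of 5% of the highest or less were set aside. Those set aside include 0.333 FPKM for Snord65 in wildtype library 2 and 0.317 FPKM for Snord4a in knockout library 2. Both are too small to be whole steps of the size found in the other genotype, so the test does not cover them. This held for 100% of 14 groups of values, against 0 of 27 groups of values from the ordinary named genes that were called (Fisher's exact test, p = 2.8e-11). The named genes are much longer, and some counted once for each genotype. Small RNA genes that were not called were not compared, so the p-value does not decide the cause. The values kept could be a few fragments scaled up by very short genes. The limma calls of these rows do not tell this apart from a genotype effect on small RNA.

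Of the 10 splits of the 6 libraries into 3 and 3, the real 1 gave 42 called genes and the highest other 3. With 10 splits a share under 0.05 cannot be reached. The 42 include the targeted gene, 6 genes in its window and 14 small RNA genes. The count therefore does not measure a wider response to the loss of TNFR2.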
